A study of Homo sapiens with 2 samples.

How the data were processed

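Total RNA of the resistant cells (T100) and of the parental SKBR3 cells (T0) was amplified, coupled to Cy3 or Cy5 and hybridised together on 2 two-colour Agilent 44K arrays. The first array held T100 in Cy5 and T0 in Cy3, and the second held the same RNAs with the dyes swapped, per the labels. The labels call the arrays technical replicates, so they were treated as 1 RNA pair, n = 1 culture per cell line.

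The deposited scanner files hold the mean intensity of each spot and the median intensity of its local background in both channels, as extracted with Agilent Feature Extraction 9.5.3.1 from design 014850, per the file headers. The same deposited files hold a log10 ratio of red over green that Feature Extraction had corrected for background and dye, per the file headers. The submitters' processing notes name Agilent Feature Extraction and limma. The authors' deposited table of T100 against T0 holds a log2 fold change, a mean log2 intensity, a p-value and an adjusted p-value per spot from limma, per the file headers. The background correction and normalization behind that table are not given in the sources used here, and its p-values rest on the 2 technical arrays. It was used only as an alternative and for the values credited to it.

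Each array had 45015 spots, of which 1639 were controls, and 41000 distinct probes. The intensities were corrected with limma 3.58.1 in R 4.3.3 by the normexp method with an offset of 50 and normalised by loess within each array, with control and outlier-flagged spots at weight 0 and left out afterwards. Before that step, 6 spots whose local background exceeded 4 times the median of their channel were given that median. This choice was made after seeing the data. With those spots as deposited, the fitted background mean of the red channel on the array with T100 in Cy3 was -368 intensity units, against -12.2 with them replaced, which compressed the ratios of that array. Both arrays were turned to T100 over T0. Unturned, their deposited ratios correlated at r = -0.915 across spots, the sign that swapped dyes give.

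Replicate spots of a probe were averaged. Probes were named through RefSeq accessions of the GRCh38.p14 gene table (23958 probes), then by current symbol (2755) or unique synonym (1032), and 13255 probes stayed unnamed. Probe coordinates are those of the files, on hg18. Each gene was read from its brightest probe. It counted as measured when that probe was well above background, by the scanner's flag, on both arrays in the cell line where it was brighter, which left 12469 of 17757 genes. A gene was called higher or lower when its log2 ratio passed 1 in the same direction on each array. The count of genes that passed 2-fold towards the same dye on both arrays measures the dye bias of single genes left after loess. XIST, Y-linked genes and probes placed on Y were left out.

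With 1 RNA per cell line there is no replicate check of any difference, and no test was made. Values are mean log2 ratios ± SD over the 2 dye orientations (n = 2), which covers technical error only, and the number of arrays limits the precision. The median of a list is taken over the mean ratios of its members, and the SD beside it is that of the medians of each array. Where a list's median lies outside the medians of both arrays, these are given in place of the SD. Where a probe was not well above background in the dimmer cell line on both arrays, the brighter line's level was set against the higher of the lowest signal among probes well above background and the probe's own signal, per array after loess and Aquantile scaling. The result is written as at least N-fold. The median ratio of each of 43 gene lists was placed among 10000 random lists of the same size matched on mean intensity in 20 bins, as a description of these arrays. A list was said to stand apart when its median fell outside the central 95% of random lists. About 2.15 of 43 lists would do so by chance if genes were independent. The lists, the thresholds and all alternatives except the high-background spots were fixed before the data were examined.

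Genes are named by 3 rules fixed at the same time. These are the 10 highest and 10 lowest called genes, a set of 16 genes tied to HER2 drugs or sorafenib, and up to 4 called members per described list with the largest ratios. Some of the genes so chosen, and a list, are left out of the text and plots. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The alternatives were Agilent's own ratio, normexp with an offset of 10, no background correction, median centring, scaling between arrays, the mean over a gene's probes, no filter on dim probes, a filter on both cell lines, each array alone, saturated probes left out, the authors' deposited log2 fold change, a 2-fold rule on the mean, unmatched random lists, and the high-background spots left in.

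The procedure was tested on simulated data with 200 genes changed by each known fold among 10886 genes in the comparison of T100 with T0. It called 10% of genes changed exactly 2-fold, 100% of those changed 4-fold and 100% of those changed 8-fold. The median recovered log2 ratio was 0.90, 1.84 and 2.79, so ratios are slightly compressed. None of the unchanged genes was called (0 of 10286). All simulated genes were well above background in both lines on both arrays, and the noise of the log ratio had the same SD at all intensities. False calls among dim or very bright genes were therefore not tested. Of 100 simulated lists of 15 unchanged genes 2 stood apart, and all 10 lists shifted by 0.5 did.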

Results

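Expression was compared between T100 and T0 cells. SKBR3 is a human breast cancer line in which the ERBB2 gene, encoding the receptor HER2, is amplified. T100 is described as derived from it by 12 months of culture with trastuzumab, an antibody against HER2, at 100 µg/mL. It is also described as resistant to trastuzumab and to lapatinib, an inhibitor of the EGFR and HER2 kinases. T0 is described as the parental culture. The study's title asks whether the resistant cells still rely on HER2 and whether they respond to sorafenib, a kinase inhibitor. One RNA per line was hybridised on 2 arrays with swapped dyes. On the array with T100 in Cy5, 62.4% of spots were well above background for T100 and 54.6% for T0, and on the swapped array 55.8% and 57.2%. All values below are mean log2 ratios of T100 over T0 ± SD over the 2 orientations (n = 2, technical error only), unless a fold is written.

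The cultures differed widely. Of 12469 measured genes, 1395 were at least 2-fold higher in T100 on both arrays and 1662 were at least 2-fold lower, together 24.5%. At the stricter bound of 8-fold, 112 were higher and 234 lower. By comparison, 4 genes passed 2-fold towards the same dye on both arrays. Among the highest genes in T100 were LGALS3 (6.34 ± 0.64, T0 well above background on 1 of 2 arrays), GPX1 (6.08 ± 1.29), GALNT14 (6.01 ± 0.49), DUSP6 (at least 56.1-fold higher) and RHOD (5.62 ± 1.16), followed by NR2F1 (5.43 ± 1.15), APOBEC3D (5.40 ± 0.46, T0 well above background on 1 of 2 arrays), HOXB2 (at least 34.5-fold higher) and TFAP2B (5.29 ± 0.12). LGALS3 encodes galectin-3, GPX1 a glutathione peroxidase, DUSP6 a phosphatase that inactivates ERK, and NR2F1, HOXB2 and TFAP2B are transcription factors. The lowest were GPNMB (-7.41 ± 0.023, T100 well above background on 1 of 2 arrays), LDHB (-6.75 ± 0.22, T100 well above background on 1 of 2 arrays), ALDH2 (-6.46 ± 0.056), CBR1 (-6.36 ± 0.014, T100 well above background on 1 of 2 arrays) and GDPD3 (-6.32 ± 0.71), followed by FHL2 (-6.18 ± 0.25), PROSER2 (-6.03 ± 0.25), CX3CL1 (-5.95 ± 0.45), S100A4 (-5.93 ± 0.67) and S100A6 (-5.80 ± 1.53). Another measured probe was much weaker for GPNMB (-1.75), PROSER2 (-1.62), CX3CL1 (-1.60) and HOXB2 (3.096), so their ranks rest on the brightest probe. GPNMB encodes a transmembrane glycoprotein, LDHB a lactate dehydrogenase subunit, ALDH2 a mitochondrial aldehyde dehydrogenase and CX3CL1 the chemokine fractalkine.

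**Figure D1:**
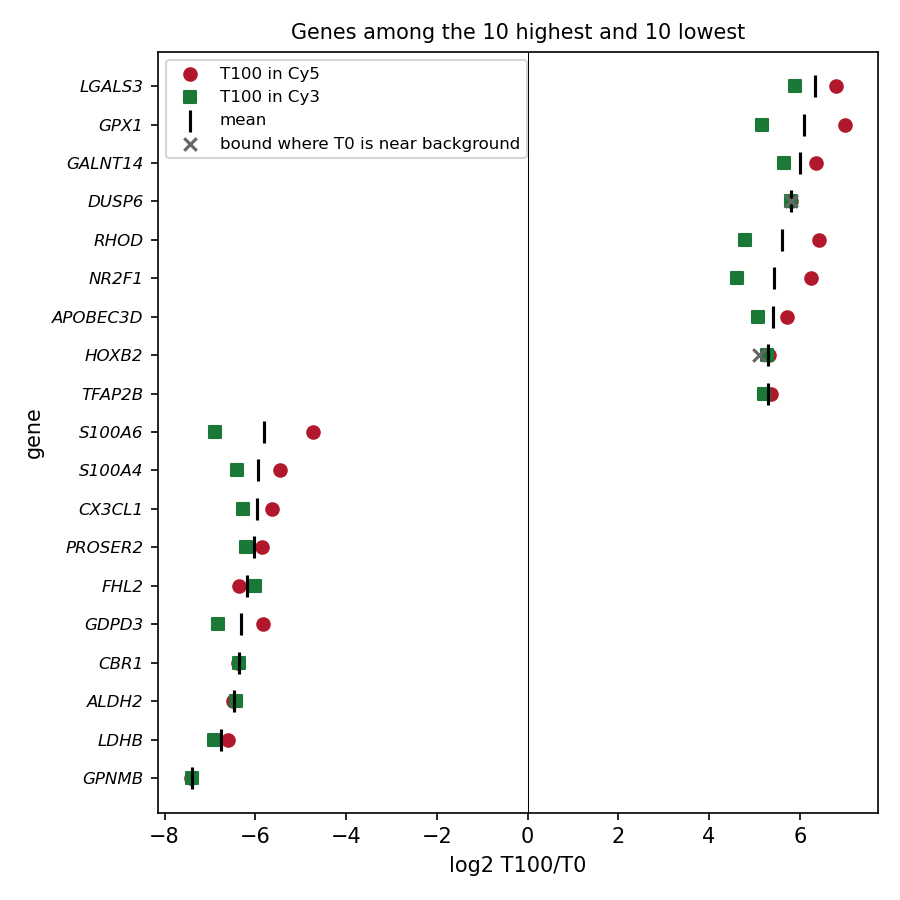
Genes among the 10 highest and 10 lowest that passed 2-fold on both arrays, with the log2 ratio of T100 over T0 on the horizontal axis. Circles are the array with T100 in Cy5, squares the swapped array, bars the mean and crosses a bound where T0 was near background; the means run from -7.41 for GPNMB to 6.34 for LGALS3.

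ERBB2 itself was lower in T100. Its main probe, on chromosome 17 at 35138355 to 35138414 (hg18), gave -2.69 ± 0.0054, a 6.46-fold lower level, and the 10 replicate spots of that probe had an SD of 0.026 and 0.024 on the 2 arrays. A second probe at 35120176 to 35120235 gave -2.39 ± 0.18. Among the other receptors of the family, EGFR was at least 19.7-fold lower, since its probe was not well above background in T100, and ERBB4 (1.40 ± 6.5e-06, T0 well above background on 1 of 2 arrays) was higher. ERBB3 (0.62 ± 0.018) passed 2-fold on neither array, and its measured probes ranged from -0.44 to 0.62. The 4 receptors had a median of -1.04 ± 0.012 at percentile 3.65 of random lists, within the central 95%, and at 1.63 when a gene's probes were averaged. ERBB ligands had a median of -0.34 ± 0.095, with 1 higher and 0 lower of 4 measured, the higher one being AREG, amphiregulin, at least 2.01-fold. Genes of HER2 stability, shedding and masking had a median of -0.12 ± 0.26 and 2 higher and 2 lower of 14 measured, namely MUC1 (-4.37 ± 0.55) and CD44 (at least 2.36-fold lower) on the lower side and TOB1 (1.11 ± 0.12) and HAS3 (at least 2-fold higher) on the higher.

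Genes named beforehand for HER2-drug resistance or sorafenib were mixed. IGF1R (1.43 ± 0.35), the type 1 insulin-like growth factor receptor, and CDKN1B (1.78 ± 0.25), which encodes the cell cycle inhibitor p27, were higher in T100. MET, the hepatocyte growth factor receptor, was at least 3.55-fold lower. No 2-fold difference on both arrays was measured for MCL1 (-0.27 ± 0.086), BIRC5 (-0.22 ± 0.19), BRAF (-0.18 ± 0.0095) and PIK3CA (0.20 ± 0.13). MCL1 and BIRC5 encode survival proteins, and BRAF a kinase that sorafenib inhibits. MUC4 was not well above background in either line. Of 7 measured sorafenib target kinases, RET (2.76 ± 0.29, T0 well above background on 1 of 2 arrays) was higher and CSF1R (-4.41 ± 0.46) lower, and their median was -0.048 ± 0.081, within the range of random lists.

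Genes around ERBB2 on 17q12-q21 were lower as a group. Of 19 measured genes of the list, 17 were at least 2-fold lower and none (0) was higher, with a median of -2.19 ± 0.19 at percentile 0 of random lists. The lowest were GSDMB (-5.78 ± 0.86), CDK12 (-3.41 ± 0.13), RARA (-3.31 ± 0.051) and PPP1R1B (-3.10 ± 0.014), and the adaptor gene GRB7 (-2.19 ± 0.24) was lower too. PNMT and ORMDL3 did not pass 2-fold, at -0.092 ± 0.13 and -0.65 ± 0.14. The list spans chromosome 17 from 34814540 to 35799294 (hg18). The rest of chromosome 17, 774 measured genes, had a median of -0.063. That median covers stretches of neighbouring genes that lie low and others that lie high, so it does not show that low values were confined to the list's span.

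**Figure D2:**
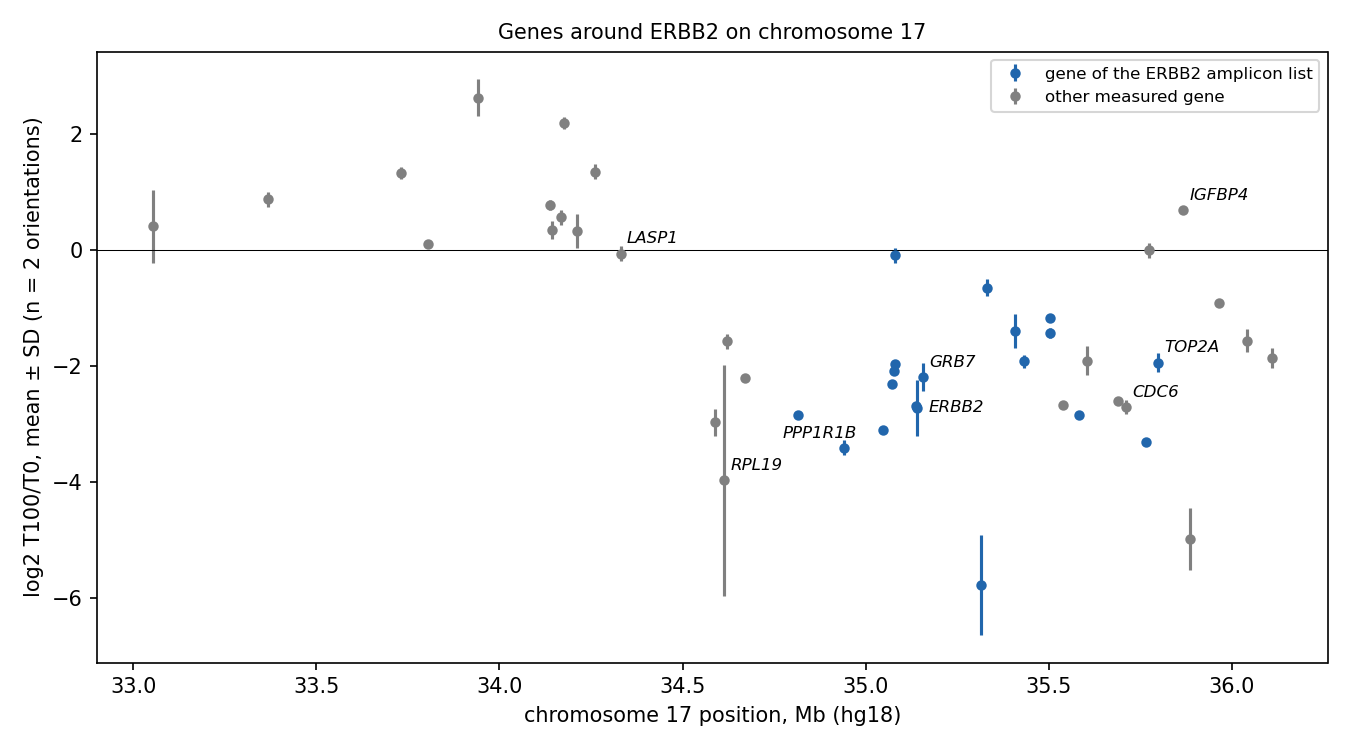
Mean log2 ratio of T100 over T0 (vertical axis, bars ± SD over 2 orientations) of the measured genes on chromosome 17 by hg18 position in Mb, with genes of the ERBB2 list in blue and others in grey. Values lie low from CACNB1 (-2.97) through ERBB2 (-2.69) to TOP2A (-1.94), between LASP1 (-0.059) and IGFBP4 (0.69), with single exceptions such as PNMT. Beyond IGFBP4 some genes are low again, such as TNS4 (-4.98) and SMARCE1 (-1.57), so no border is set there.

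Epithelial and hormone-related genes differed in both directions. Luminal epithelial genes were split (7 higher and 8 lower of 24 measured, median 0.093 ± 0.037), with GATA3 (4.45 ± 0.39), a luminal transcription factor, higher and MUC1 (-4.37 ± 0.55), BCAS1 (-3.80 ± 0.54) and KRT8 (-3.08 ± 1.06) lower. Basal epithelial genes stood apart on the lower side (3 higher and 9 lower of 19 measured), with a median of -1.02 ± 0.11 at percentile 0. Examples were CRYAB (-4.55 ± 0.59), KRT15 (-3.79 ± 0.20), TRIM29 (-2.81 ± 0.14) and CAV1 (at least 5.8-fold lower). Estrogen receptor targets stood apart on the higher side, with 6 higher and 0 lower of 13 measured and a median of 0.97 ± 0.093 at percentile 99.96, but at percentile 68.8 without the filter on dim probes. Its highest members were CCND1 (4.52 ± 0.66), RET (2.76 ± 0.29, T0 well above background on 1 of 2 arrays), XBP1 (2.44 ± 0.22) and CA12 (1.95 ± 0.10). The measured probes of CCND1, cyclin D1, disagreed, from -1.65 to 4.52. Apocrine and androgen response genes had 8 higher and 2 lower of 19 measured with a median of 0.21 (0.26 and 0.32 on the 2 arrays), within the range of random lists. Among them were TFAP2B (5.29 ± 0.12) and CLCA2 (4.90 ± 0.55, T0 well above background on 1 of 2 arrays) and on the lower side SERHL2 (-4.58 ± 0.77). Breast stem-cell associated genes (2 higher and 3 lower of 8 measured, median -0.42 ± 0.017) included ALDH1A3 (-4.92 ± 0.81, T100 well above background on 1 of 2 arrays) and CD44 (at least 2.36-fold lower) on the lower side and ITGA6 (at least 10.4-fold higher) and BMI1 (1.32 ± 0.068) on the higher.

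Genes that report ERK pathway output stood apart on the higher side (8 higher and 2 lower of 16 measured), with a median of 0.87 ± 0.017 at percentile 99.96. Besides CCND1 the top members were DUSP6 (at least 56.1-fold higher), ETV5 (at least 4.33-fold higher) and DUSP5 (2.34 ± 0.066), which are induced by ERK signalling. That percentile was 90.6 among genes measured in both lines. CDK inhibitors and G1 regulators stood apart on the higher side as well (8 higher and 1 lower of 16 measured, median 0.86 ± 0.042, percentile 99.98), led by CCND1, CDKN1C (2.35 ± 0.056) and CDKN1B, with CDK6 at least 3.06-fold lower. Other receptor tyrosine kinases went both ways (6 higher and 5 lower of 18 measured, median -0.15 ± 0.032), with FGFR4 (4.36 ± 0.68) and ROR2 (2.93 ± 0.39, T0 well above background on 1 of 2 arrays) higher and FGFR3 (-3.75 ± 0.076) and EPHB6 (-3.18 ± 0.091, T100 well above background on 1 of 2 arrays) lower. PI3K-AKT-mTOR components had 3 higher and 3 lower of 24 measured and a median of -0.018 ± 0.065. Their extremes were RPTOR (-2.09 ± 0.15), INPP5D (at least 3.32-fold lower), IRS1 (1.96 ± 0.11, T0 well above background on 1 of 2 arrays) and RPS6KB1 (1.37 ± 0.12).

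Proliferation genes were split evenly (3 higher and 3 lower of 30 measured, median 0.034 (0.044 and 0.16 on the 2 arrays)). CDC6 (-2.71 ± 0.12) and TOP2A (-1.94 ± 0.16), both on 17q near ERBB2, were lower and MCM3 (2.20 ± 0.041) and MCM2 (1.60 ± 0.20) higher. The BCL2 family had 2 higher and 1 lower of 16 measured, with BIK (1.52 ± 0.017) and BCL2L11 (1.31 ± 0.10) higher and BAK1 (-1.76 ± 0.086) lower around a median of 0.27 ± 0.084. Inhibitors of apoptosis and death receptors had a median of 0.15 ± 0.055, with TNFSF10 (1.34 ± 0.035) and CFLAR (-1.18 ± 0.10) as the 2 called members. The 2 measured probes of CFLAR disagreed in sign, at -1.18 and 0.73.

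Interferon-stimulated genes gave the highest list median, 1.60 ± 0.087 at percentile 100, with 14 higher and 2 lower of 25 measured. Examples were BST2 (3.54 ± 0.998), OASL (2.83 ± 0.16), IFI27 (2.72 ± 0.21) and IFI6 (2.71 ± 0.36), but the 2 measured probes of IFI6 gave -0.027 and 2.71. MHC class I genes had 5 higher and 3 lower of 17 measured and a median of 0.27 ± 0.14, within the range of random lists, although the heavy chain genes HLA-C (3.60 ± 0.42), HLA-G (2.57 ± 0.63) and HLA-B (1.93 ± 0.51) were higher (these genes are near-identical in parts, so single values are uncertain). MHC class II genes had a median of -0.45 (-0.40 and -0.41 on the 2 arrays), and HLA-DMB was at least 2.05-fold higher. NF-kB targets, cytokines and chemokines stood apart on the lower side (1 higher and 5 lower of 18 measured, median -0.56 ± 0.16, percentile 0.73), with CCL2 (-4.34 ± 0.18, T100 well above background on 1 of 2 arrays), TNFAIP2 (-3.96 ± 0.23), RELB (-2.63 ± 0.042) and TNF (-2.41 ± 0.055, T100 well above background on 1 of 2 arrays). That percentile was 2.58 on the array with T100 in Cy3 alone and, among genes measured in both lines, 24.4.

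Markers of immune cells, fibroblasts, endothelial cells and adipocytes were mostly not higher in T100. Of 58 marker genes on the array, 1 was at least 2-fold higher in T100, COL1A1 (1.31 ± 0.31), and 8 were lower. Immune cell markers had a median of -0.82 ± 0.025 at percentile 1.19, with CSF1R (-4.41 ± 0.46) and CORO1A (-4.38 ± 0.61), but at 2.91 on the array with T100 in Cy5 alone and 4.13 without the filter on dim probes. Medians were -0.43 ± 0.092 for fibroblast markers, where S100A4 (-5.93 ± 0.67) and COL5A2 (-1.51 ± 0.079, T100 well above background on 1 of 2 arrays) were lower, -0.45 ± 0.072 for endothelial markers, where ENG (-3.56 ± 0.13) and ESAM (-2.55 ± 0.12) were lower, and 0.14 ± 0.23 for adipocyte markers, where PPARG was at least 3.13-fold lower.

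Several lists of adhesion and matrix genes stood apart on the lower side. Integrins and matrix genes had 3 higher and 14 lower of 26 measured and a median of -1.13 ± 0.021 at percentile 0. TIMP2 (-5.37 ± 0.71) and FN1 (-3.72 ± 0.024, T100 well above background on 1 of 2 arrays), a metalloproteinase inhibitor and fibronectin, were lower, and TNC (4.26 ± 1.17) and ITGA6 (at least 10.4-fold higher) were higher. TGF-beta targets had 1 higher and 7 lower of 17 measured and a median of -0.87 (-0.87 and -0.76 on the 2 arrays) (percentile 0.04), with CCN2 (-3.55 ± 0.25) and TGFBI (at least 9.37-fold lower) lower and ID2 (2.20 ± 0.058) higher. Mesenchymal and EMT genes had 0 higher and 4 lower of 10 measured and a median of -0.83 ± 0.20 (percentile 0.72), including CALD1 (at least 4.57-fold lower) and SNAI1 (-2.22 ± 0.10, T100 well above background on 1 of 2 arrays); this median turned to 0.0027, at percentile 54.7, among genes measured in both lines. WNT pathway genes stood apart on the higher side (4 higher and 2 lower of 17 measured, median 0.68 (0.68 and 0.73 on the 2 arrays), percentile 99.93), with FZD4 (2.998 ± 0.064) and RNF43 (1.78 ± 0.093, T0 well above background on 1 of 2 arrays) higher and WNT5A (-2.85 ± 0.12) and WNT7B (-1.94 ± 0.013) lower. NOTCH pathway genes had a median of -0.41 ± 0.089, and HES1 (-3.42 ± 0.029) and DLL3 (-3.24 ± 0.088, T100 well above background on 1 of 2 arrays) lay opposite to DLL1 (at least 5.86-fold higher) and JAG2 (2.55 ± 0.31).

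Genes of cholesterol synthesis stood apart on the higher side, 10 higher and 0 lower of 23 measured, with a median of 1.13 (0.94 and 0.85 on the 2 arrays) at percentile 100. Examples were INSIG1 (2.61 ± 0.14), HSD17B7 (2.11 ± 0.051), NSDHL (1.49 ± 0.15) and HMGCS1 (1.49 ± 0.19). Fatty acid synthesis genes were split (4 higher and 4 lower of 16 measured, median -0.26 ± 0.0068), the desaturases FADS2 (2.83 ± 0.033) and FADS1 (2.15 ± 0.12, T0 well above background on 1 of 2 arrays) being higher and ME1 (-3.40 ± 0.044, T100 well above background on 1 of 2 arrays) and FABP5 (at least 7.23-fold lower) lower. ABC transporters, many of which export drugs or lipids, stood apart on the higher side (5 higher and 1 lower of 10 measured, median 1.20 ± 0.033, percentile 99.97), led by ABCC3 (3.42 ± 0.0016), ABCC11 (3.02 ± 0.94), ABCC6 (2.73 ± 0.047) and ABCG1 (2.16 ± 0.00013), but their percentile was 70.8 without the filter on dim probes. Hypoxia and glycolysis genes had 4 higher and 7 lower of 26 measured and a median of -0.46 (-0.35 and -0.37 on the 2 arrays) at percentile 1.49, but at 4.77 and 5.64 on each array alone. Within it, ANGPTL4 (-4.18 ± 0.073) and ADM (-4.14 ± 0.014) were lower and ENO2 (4.34 ± 0.31) and EGLN3 (3.69 ± 0.023) higher.

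Stress and turnover lists stayed within the range of random lists in the main setting. NRF2 and xenobiotic metabolism genes had 0 higher and 6 lower of 18 measured and a median of -0.43 ± 0.15, with GSTM3 (-5.05 ± 0.66), CYP1A1 (-3.49 ± 0.11), AKR1B10 (at least 4.25-fold lower) and UGT1A6 (-1.98 ± 0.039), and reached percentile 2.04 on the array with T100 in Cy5 alone. For ATF4 and amino-acid stress genes the median was 0.23 ± 0.20, with SLC7A5 (-3.65 ± 0.17), PSAT1 (-3.45 ± 0.11, T100 well above background on 1 of 2 arrays) and ATF3 (-2.34 ± 0.0046) lower and CBS (3.24 ± 0.50) higher, and the percentile was 97.7 among genes measured in both lines. The unfolded protein response list had a median of -0.21 ± 0.0067, with XBP1 higher and DNAJB9 (-1.42 ± 0.013), HSP90B1 (-1.09 ± 0.11) and SYVN1 (-1.09 ± 0.025) lower, the 2 measured probes of SYVN1 giving -1.09 and 0.0091. Heat shock genes had a median of -0.42 ± 0.18, with HSPB1 (-3.37 ± 2.03) and HSPB8 (at least 7.38-fold lower) lower and SERPINH1 (1.83 ± 0.0002) higher. Lysosome and autophagy genes had 1 higher and 7 lower of 22 measured and a median of -0.27 ± 0.10, with WIPI1 (-3.96 ± 0.15), GABARAPL1 (-2.94 ± 0.09, T100 well above background on 1 of 2 arrays), CTSD (-2.54 ± 0.33) and CTSL (-2.51 ± 0.17).

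Cancer-testis antigens, normally restricted to germ cells, stood apart on the lower side, with 0 higher and 7 lower of 12 measured and a median of -2.02 ± 0.21 at percentile 0. The lowest were MAGEA6 (-4.46 ± 0.32), MAGEA12 (-4.42 ± 0.65), CTAG2 (-4.12 ± 0.62) and MAGEA4 (-3.61 ± 0.028, T100 well above background on 1 of 2 arrays), members of families of similar sequence. Common reference genes had a median of 0.19 (0.10 and 0.041 on the 2 arrays), with REEP5 (1.59 ± 0.32) and TFRC (-1.24 ± 0.073) as the 2 called members. Ribosomal protein genes had a median of -0.021 ± 0.80, but the arrays disagreed, at 0.54 and -0.59 (percentiles 99.1 and 2.39). Their called members with the largest ratios were RPL19 (-3.97 ± 1.99), RPS13 (-2.59 ± 0.40), RPL30 (1.44 ± 0.31) and RPL4 (1.21 ± 0.0055). In all, 16 of 43 lists stood apart, 9 on the lower and 7 on the higher side. With genes near background set at their bound the count was 17. The size of many list medians depended on the setting, and the extremes often came without the filter on dim probes or with Agilent's own log ratio. Over the alternatives they ranged over -4.20 to -0.62 for cancer-testis antigens, -1.36 to -0.26 for integrins and matrix, -2.31 to -0.46 for basal epithelial, -1.65 to -0.74 for TGF-beta, -0.64 to -0.092 for NF-kB, -2.65 to 0.0027 for mesenchymal, -0.53 to -0.26 for hypoxia and -1.07 to -0.091 for immune marker genes. On the higher side they ranged over 0.70 to 2.40 for interferon-stimulated, 0.041 to 2.01 for ABC transporter, 0.033 to 1.83 for estrogen receptor target, 0.32 to 1.12 for ERK output and 0.34 to 1.10 for WNT genes.

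**Figure D3:**
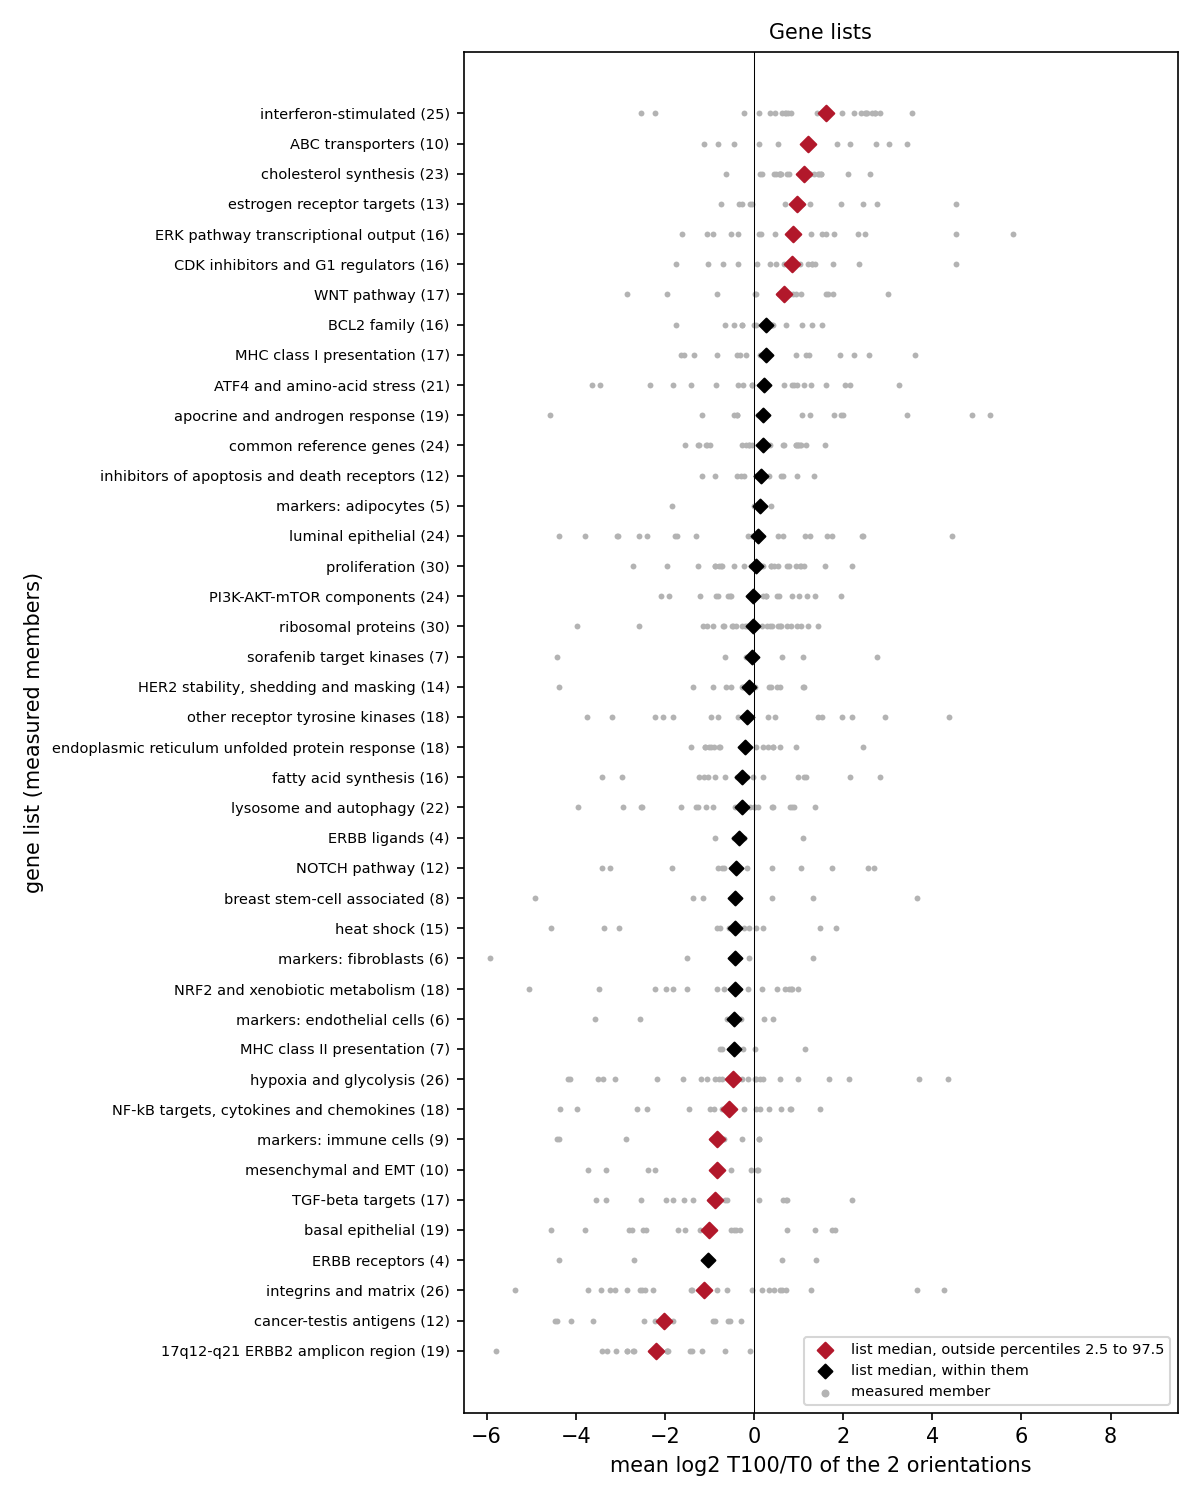
Mean log2 ratio of T100 over T0 (horizontal axis) of the measured members (grey points) and the median (diamonds) of the gene lists, with the number of measured members beside its name. Red diamonds are the 16 medians outside the central 95% of matched random lists, from -2.19 for the ERBB2 region to 1.60 for interferon-stimulated genes.

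The 2 orientations gave similar ratios across genes, with Pearson r = 0.968 and Spearman rho = 0.956 over 12469 genes, which are not independent replicates. Probes of a gene disagreed in places. Among the called genes named here, another measured probe had a mean below 2-fold for IGF1R (0.64), CDKN1B (0.79), RARA (-0.57), ABCC6 (0.95), DLL3 (-0.81), RPS6KB1 (0.79), FZD4 (0.64), CAV1 (-0.69), ALDH1A3 (-0.74), REEP5 (0.36), CA12 (0.47), FABP5 (-0.98) and ROR2 (0.55), besides the genes given above. It passed 2-fold in the mean but was over 2 log2 units weaker for FGFR3 (-1.25) and ME1 (-1.02). The median SD of a gene was 0.11. It was larger for the brightest genes, 0.46 for 186 genes with a mean log2 intensity over 16, a group that holds KRT8 and many ribosomal genes. In the authors' deposited table, 11098 of 31546 spots with a value had an adjusted p below 0.05 by limma, a test over 2 technical arrays that does not cover differences between cultures. In the authors' deposited table the ERBB2 main probe lay between -2.69 and -2.64 over its 10 spots, with a limma adjusted p of at most 0.000152. The log2 fold changes of the authors' deposited table correlated with the recomputed ratios at r = 0.992 across spots.

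**Figure D4:**
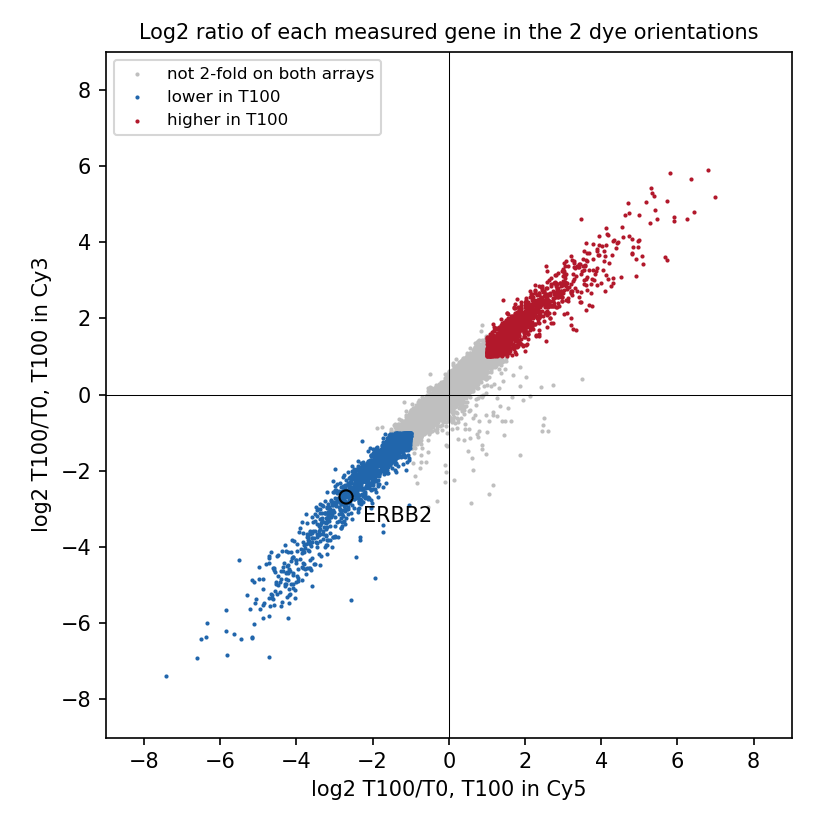
Log2 ratio of T100 over T0 of each measured gene on the array with T100 in Cy5 (horizontal) and on the dye-swapped array (vertical). Red points are the 1395 genes at least 2-fold higher on both arrays, blue points the 1662 lower ones, and ERBB2 is circled.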

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

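Probes that could not be tied to a gene symbol were not used in any comparison, yet many of them differed. Of 5367 such measured probes, 493 were at least 2-fold higher in T100 on both arrays and 507 at least 2-fold lower, against 3 that passed 2-fold towards the same dye.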

How the results depend on the processing

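The high-background alternative was chosen after seeing the data. The other alternatives were planned. Counts of genes stayed within 1.5 times the reported ones under all alternatives. Higher genes ranged from 1149 with high-background spots left in to 2085 with Agilent's own log ratio, and lower genes from 1129 with median centring to 2169 with Agilent's own log ratio. With the high-background spots left in, 1135 were lower. Median centring moved the median of all measured genes to 0.15 and the higher share of calls from 45.6% to 54.4%. Of the 3057 called genes, 2364 were also called under median centring and 2274 with the high-background spots left in. Leaving the dim probes in added no called gene.

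The ERBB2 ratio moved by more than its very small SD but kept its size. It was -2.66 with Agilent's own log ratio, -2.68 with an offset of 10, -2.47 with median centring, -2.54 as the mean of its probes, -2.67 in the authors' deposited table and -2.68 with the high-background spots left in. The correlation of the orientations was 0.963 with Agilent's own log ratio, 0.931 with median centring, 0.973 with a gene's probes averaged, 0.963 without the dim filter, 0.963 for genes measured in both lines and 0.94 with the high-background spots left in. The cause of these shifts was not tested. Neither a single array nor the authors' deposited table gives such a correlation.

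The 160 genes chosen by the naming rules that passed the 2-fold rule kept their direction in all 2076 alternative values. For part of the settings this was fixed in advance. A called gene has the same direction on each array alone. The filter settings for dim probes reuse the main ratios, and scaling between arrays keeps the sign. For the 16 lists standing apart, 207 of 208 alternative medians kept their direction, the exception being mesenchymal and EMT genes at 0.0027 among genes measured in both lines, a setting that leaves out genes near background in T100. Of those lists, 9 stood apart under all 14 alternatives. The others did so under fewer, 13 for ABC transporters and for estrogen receptor targets, 12 for immune markers and for mesenchymal genes, 11 for NF-kB targets and 10 for ERK output and for hypoxia and glycolysis. The number standing apart ranged from 12 with no filter on dim probes to 17. Another 5 lists stood apart only under some alternatives, among them ribosomal proteins under 2 and NRF2, ATF4 and ERBB receptor genes under 1 each. Spots with a log2 fold change in the authors' deposited table differed from the recomputed ratios by a median of 0.071, and by 0.018 when the high-background spots were left in. No paired analysis was possible because each cell line gave 1 RNA. Signal over background limits the folds of 371 called genes to bounds.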

Other observations

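The gene families and windows in this part, and the tests on dye bias, on other cell types and on separate lines, were chosen after the data were seen. The tests on the segment, on related neighbours and on adjacent windows were set before their results were seen.

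Several gene families of similar sequence or position differed as groups. Zinc finger genes of 19p12 had a higher median in T100 (17 higher and 0 lower of 23 measured, median 1.84 ± 0.31, percentile 100). Histone genes of chromosome 6 did too (19 higher and 0 lower of 49 measured, median 0.75 ± 0.021, percentile 100), although most of them did not pass 2-fold. S100 genes, which encode small calcium-binding proteins, had a lower one (0 higher and 11 lower of 16 measured, median -2.54 ± 0.033, percentile 0). S100A8 (-5.74 ± 0.13), S100P (-5.26 ± 0.77) and S100A9 (-4.98 ± 0.80) were among the lowest besides S100A4 and S100A6. The keratin median was low too (3 higher and 15 lower of 31 measured, median -1.21 ± 0.36, percentile 0), with KRT4 (-5.76 ± 0.84), KRT83 (-4.83 ± 0.92) and KRT80 (-4.59 ± 0.0064) at the low end. Some keratins lay in low chromosome 17 windows of 25 neighbouring measured genes, WIPF2 to KRT36 (-0.91) and KRT13 to GHDC (-1.33). The chromosome 12 windows GPD1 to KRT81 (-0.090) and KRT86 to MYG1 (-0.38) were less low. Random lists were not matched on position, so gene family and position were not separated. Annexins (2 higher and 4 lower of 9 measured, median -1.15 ± 0.23, percentile 0.27) and aldehyde dehydrogenases (7 higher and 4 lower of 14 measured, median 0.79 ± 0.034, percentile 99.6) had members on both sides, such as ANXA11 (-4.52 ± 0.17) and ANXA2 (2.42 ± 0.10) and ALDH1L1 (-4.19 ± 0.50) and ALDH4A1 (2.54 ± 0.069). The symbol pattern for aldehyde dehydrogenases missed ALDH2 (-6.46 ± 0.056), which was lower. Their count, median and percentile hold without ALDH2, and the median would be lower with it. Glutathione S-transferases (3 higher and 4 lower of 14 measured, median -0.22 ± 0.028, percentile 20.8) and tubulins (0 higher and 1 lower of 13 measured, median 0.20 ± 0.21, percentile 79.4) did not stand apart. Of 3 measured APOBEC3 genes, 2 were higher, APOBEC3B (4.50 ± 0.64) and APOBEC3D (5.40 ± 0.46, T0 well above background on 1 of 2 arrays). Over all alternatives the medians kept their sign, from 1.09 to 2.83 for the zinc finger genes, 0.74 to 0.98 for histones, -3.32 to -2.15 for S100 genes and -2.04 to -0.79 for keratins. Members of these families are similar in sequence, so single values are uncertain.

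Neighbouring genes on a chromosome tended to differ in the same direction, though most of the variance of single-gene ratios lay within windows. Differences between windows held 14.7% of it, a share that was not compared with shuffles. Medians of 488 windows of 25 neighbouring measured genes had an SD of 0.42, against at most 0.21 in 1000 shuffles of the gene order, and 7 windows lay below and 2 above all shuffled ones. The lowest windows were chromosome 17 from 34259890 to 35605009 (median -2.19 ± 0.089, RPL23 to RAPGEFL1), chromosome 8 from 110638406 to 124894039 (median -1.60 ± 0.084, EBAG9 to FAM91A1) and chromosome 7 from 101747567 to 106631218 (median -1.40 ± 0.074, SH2B2 to COG5), and the highest were chromosome X from 153282383 to 154908487 (median 1.31 ± 0.14, RPL10 to WASH2P) and chromosome 17 from 70276798 to 71032192 (median 1.24 ± 0.0038, NHERF1 to TSEN54). With 1 gene kept among neighbours that share the leading letters of their symbol, the SD was 0.40, above the highest shuffle of 0.21. Clusters thinned by this rule, such as zinc finger genes, therefore do not account for all of it. Histone and S100 symbols, in which a digit follows the opening letter, were not thinned, so the share of those clusters was not tested. Medians of adjacent windows correlated at 0.44, against at most 0.15 in shuffles, as gains or losses of long segments would give; without DNA measurements this stays a hypothesis, and shared regulation of neighbours was not tested.

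The lower expression around ERBB2 was weighed in the same way. Dye bias is argued against by the list's median of -2.06 in the weaker orientation. That value follows from the 17 of 19 genes called lower on each array, so it is no separate support. It does not test compression of bright spots, which would shrink ratios rather than lower them. A change of the whole segment is a candidate explanation. The 5 measured genes inside the segment that were not on the list lay beyond ERBB2, from 35539591 (MSL1) to 35773541 (GJD3). They sample only that side of it. Their median was -2.60, and 4 of them were at least 2-fold lower. Fewer copies of the amplified segment in T100 could give this, as could lower transcription of the region, and RNA ratios cannot separate these.

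The share of genes that differ at least 2-fold, 24.5%, was weighed against technical explanations, though a normalization error that follows the sample was not tested. Dye bias of single genes is argued against by the genes 2-fold towards the same dye, 0.131% of the number called. Immune cells, fibroblasts, endothelial cells or adipocytes in T100 are argued against, though weakly, by the 1.72% of their 58 markers on the array that were higher. Higher were 0 of 9 measured immune, 1 of 6 fibroblast, 0 of 6 endothelial and 0 of 5 adipocyte markers. Among all measured genes the count was 1395 of 12469. Of the 58 markers, 27 were not well above background in T100 on either array, so they could not be called higher. Another 8 markers were lower in T100, and such cells in T0 were not tested. Separate lines or clones were predicted to give genes near background in one line and at least 10-fold brighter in the other, in both directions. This prediction was met by 15 genes, 7 brighter in T100 and 8 in T0. Long adaptation in culture may give such genes too, so their count cannot tell it apart from separate lines or clones. Picked after its value was seen, CDH1, the gene of E-cadherin, a protein SKBR3 is known to lack, was at least 4.32-fold higher in T100. A second resistant culture derived from T0 would show which differences recur. It would not show whether this T100 culture descends from T0, and no DNA was measured here.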
